A study of Drosophila melanogaster with 6 samples.

How the data were processed

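The series holds RNA-seq of adult male Drosophila melanogaster collected 12 h after injection of Micrococcus luteus, a Gram-positive bacterium. There were 3 libraries from control flies and 3 from flies that overexpressed the long noncoding RNA CR33942. Per the labels, the control flies carried a temperature-sensitive Gal80 repressor and the Tub-Gal4 driver over an attP40 landing site, and the overexpressing flies drove the RNA through the same kind of driver system. Strain and overexpression therefore differ together between the groups. The labels do not say how many flies went into a library or whether the libraries came from separate pools, so p-values measure the spread between these libraries, which may be technical.

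Per the labels' protocols, mRNA was selected with poly-T beads, fragmented and sequenced as paired ends. Reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, per the labels' protocols. The authors tested differential expression with DESeq2, per the labels' protocols. The genome build was dm6, per the submitters' processing notes. Whether counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart, and copies of near-identical genes (cecropins, attacins, Hsp70) can share reads. The deposited table gives 1 FPKM value per gene and library (fragments per kilobase of gene and of reads sequenced), and the authors' step from counts to FPKM is not given in the sources used here. Of 17558 FlyBase gene identifiers in the table, 17252 were paired with a symbol in the dm6 annotation used here, and 1640 were at 0 in every library. Coordinates are those of that annotation.

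The depth behind the values was recovered from the values themselves. FPKM multiplied by the exon length and by 1 factor per library gave whole reads in every library (tolerance 0.01 of a read) for 15276 of the 15918 genes with any value above 0, or 96.0%. For the other 642 genes a length was solved that gave whole reads (tolerance 0.001 of a read). That length was fitted, so whole reads are no independent check for these genes. The recovered reads came to between 17032191 and 19797136 per library. The library factors lay within 0.281% of median-of-ratios size factors computed on those reads, and departed by up to 2.03% from the totals, so the deposited values appear scaled by size factors rather than by totals; this was read from the values and is stated nowhere in the labels.

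Group changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, which were 12326. Log2 changes are on the log2(FPKM + 1) scale and understate the change of low genes. Group means or ratios of FPKM are given for many of the named genes. Where a group had no read, a ratio was computed against a floor of 3 reads over the 3 libraries. It is given with the lower limit of an exact 95% binomial interval on the reads. Where a group had few reads, the ratio of reads is given with that whole interval, which covers counting error only.

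Before the data were examined, 29 gene lists were fixed: immune effectors and pathways, stress, metabolism, markers of tissues that a male fly holds, female markers, clock genes and transgene markers. The 26 lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over those 26. All 29 lists were tested with fry and adjusted over the 29. Its first p tests movement one way and its mixed p tests change in either direction. Each list also has its count of calls adjusted over the list alone. The 205 tested genes whose identifier had no paired symbol entered no list, except FBgn0010381 in an alternative given below. Among them FBgn0033835 had a solved exon length shared by BaraA2 alone among annotated genes that the table lacks. The rule for named genes was fixed at the same time: CR33942; all measured antimicrobial peptide, Bomanin and Toll peptide, and transgene marker genes; the 15 largest rises and 15 largest falls among called genes whose groups did not overlap; from each other list up to 4 called members, or the 2 most abundant members where none was called; genes within 20 kb of CR33942; and genes beside attP40. Genes named outside this rule are said to have been chosen after their values were seen.

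On simulated libraries with the real genes' levels and spread (5 simulations of 12326 genes, 200 of them changed in each), the limma test called 60.4% of genes changed 1.5-fold, 79.6% changed 2-fold and 92.8% changed 4-fold, and 4.94% of its calls were unchanged genes. In 20 further simulations camera called none of 520 tests of unchanged lists, and called the antimicrobial peptide list in all 20 when its members were raised 1.5-fold; the simulated genes were independent, unlike real ones.

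The settings varied were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, replicate number as a block, eBayes without a trend, sample weights, each library left out in turn, a fold threshold, and for lists an estimated correlation. After seeing the data, 3 more were added: limma's voom on the recovered reads, the count without X-linked genes, and the antimicrobial peptide list with FBgn0010381, an abundant identifier with no paired symbol whose solved exon length is shared by the drosomycin gene Drs. Every pair of libraries was compared on the recovered reads, and no replicate pair agreed within sampling noise (chi-square per gene between 5.07 and 13.2 within groups).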

Results

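The study compared whole-transcriptome expression of infected male flies with and without overexpression of the long noncoding RNA CR33942, which the series names NANPI and sets in the context of Toll signalling and antibacterial peptide genes. The table held 3 control and 3 overexpressing libraries, all taken 12 h after injection of M. luteus. Recovered reads were 19228314, 19208127 and 17032191 in the control libraries and 19797136, 19600845 and 17368606 in the overexpressing libraries. In a principal component analysis the groups separated on the first component, which held 41.8% of the variance. Overexpressing replicate 2 stood apart from the other overexpressing libraries on the second component (19.9% of the variance), at 17.1 against -8.12 and -6.63.

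CR33942 rose 29.8-fold, the largest change of any tested gene on the log2(FPKM + 1) scale. Genes near the floor in the controls, given below, rose more by ratio, among them CG14419 and lncRNA:CR43835. The gene (FBgn0062961) lies on chromosome 2R at 18711391 to 18711951 on the plus strand and is annotated as a noncoding RNA with 503 nt of exon. Its level was 19.1 ± 0.423 FPKM in the control libraries and 568 ± 18.8 FPKM in the overexpressing libraries (SD, n = 3 each). The log2 change was 4.83 ± 0.05 (SE; limma, adjusted p = 5.74e-09). An exact two-sided permutation test of the same values gave p = 0.1, the smallest that 3 against 3 libraries allow. Of 7 genes annotated within 20 kb, 6 were tested and limma called 0 of them; 0 had an unadjusted p under 0.05, and voom on recovered reads called 0 as well. Vps51 stood at 7.36 ± 0.774 FPKM in controls and 7.61 ± 0.297 in overexpressing libraries, and Sik3 at 6.03 ± 0.157 and 5.90 ± 0.105 (SD, n = 3 each). The other neighbours named by the rule were List, Hs3st-A, CG15073 and CG15071, with adjusted p of 0.860 or more, and mir-4982, listed at 0.

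**Figure D1:**
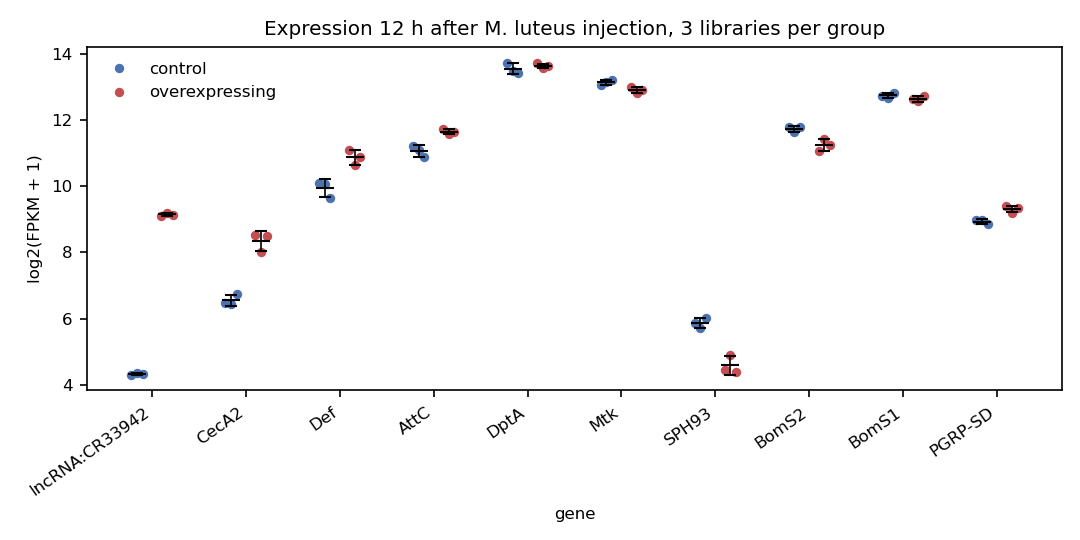
Expression of 10 genes as log2(FPKM + 1) in each of the 3 control (blue) and 3 overexpressing (red) libraries; black bars give the mean and SD of 3 libraries. CR33942 rose from 19.1 to 568 FPKM, CecA2, Def, AttC and PGRP-SD rose, SPH93 fell, and DptA, Mtk, BomS1 and BomS2 did not pass the threshold.

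Across the transcriptome 274 genes changed, 104 of them higher and 170 lower in the overexpressing flies. Most changes were small: 66 genes passed an absolute log2 change of 1, of which 43 were higher and 23 lower. Groups did not overlap for 2556 of the 12326 tested genes, or 20.7%, where chance gives 10%. Besides CR33942, the largest rises with a control level above 10 FPKM were those of CG43920, from 45.95 ± 14.99 to 269 ± 10.1 FPKM, and of Ddc. Hsp70Bb, a copy of the inducible Hsp70 chaperone gene, rose from 3.17 ± 0.883 to 38.05 ± 2.06 FPKM (log2 change 3.25 ± 0.15 SE, adjusted p = 0.0001). The largest fall was that of Jhbp4, a juvenile hormone binding protein gene, from 8.61 ± 1.962 to 0.256 ± 0.228 FPKM (SD, n = 3 each). Jhbp4 had 506 control and 16 overexpressing reads, a ratio of 0.0304 (95% interval 0.0172 to 0.0498). lncRNA:CR40469 fell from 37.4 ± 1.43 to 5.31 ± 2.87 FPKM, Yp3, which encodes a yolk protein, from 32.4 ± 1.04 to 9.04 ± 1.49 FPKM. CG31205 fell from 77.9 ± 18.3 to 27.0 ± 2.90 FPKM and HSPBAP1 from 24.6 ± 16.1 to 3.14 ± 0.0792 FPKM. CR44383, CG31775, CG42586, asRNA:CR44340 and lncRNA:CR45465 also fell, with log2 changes of -1.67, -1.50, -1.44, -1.24 and -1.21. Their ratios of mean FPKM, overexpressing to control, were 0.226, 0.296, 0.346, 0.223 and 0.309. The count of changed genes moved with the libraries used: it was 86, 70 and 122 without control replicate 1, 2 and 3, and 80, 431 and 88 without overexpressing replicate 1, 2 and 3. HSPBAP1 passed the threshold in 1 of these 6 fits, that without control replicate 2, with adjusted p up to 0.135 without control replicate 3. CR44383 passed without overexpressing replicates 1 and 2 (up to 0.112), CG31775 without control replicate 1 (up to 0.145), CG42586 without overexpressing replicate 2 (up to 0.143) and lncRNA:CR45465 without overexpressing replicate 3 (up to 0.133). CG43920, Hsp70Bb, lncRNA:CR40469, Yp3 and CG31205 passed in all 6.

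Changed genes were denser on the X chromosome than on the autosomes. Of 1887 tested X-linked genes 92 changed (4.88%), against 180 of 10193 autosomal genes (1.77%; Fisher's exact odds ratio 2.85, 95% interval 2.18 to 3.70, p = 6.43e-14 over genes, which are not independent). Among the X-linked changes 52 were higher and 40 lower, and 40 of the 66 genes past an absolute log2 change of 1 were X-linked. The X-linked share stayed above the autosomal share in each of the 6 fits without 1 library, with values between 1.62% and 5.09% on the X and between 0.366% and 3.22% on the autosomes. Of the 15 largest rises 10 lay on the X, and 5 of these had no read in any control library. Taken against a floor of 3 reads over the control libraries, CG14419 was 230-fold higher, CG12498 168-fold, CG3588 291-fold, CG3526 91.2-fold and lncRNA:CR44534 48.6-fold higher. The lower limits of the exact 95% intervals on their read ratios were smaller, at 186, 135, 237, 72.9 and 39.1 in that order. CG12498, CG14419, CG3526 and CG3588, as was noticed after their values were seen, are neighbours between 2809881 and 2924426 on the X, next to the eye colour gene w and within the bounds of kirre. The 7 annotated genes that start in that stretch had 0 reads over the control libraries and 2486 over the overexpressing libraries. Other rises on the X were those of lncRNA:CR43835, from 0.0958 ± 0.0832 to 4.26 ± 1.26 FPKM (4 and 188 reads, ratio 45.1, 95% interval 17.3 to 167). CG6788 rose from 0.0908 ± 0.120 to 3.78 ± 1.28 FPKM (6 and 256 reads, ratio 41.0, 95% interval 18.6 to 113). Cnx14D, a calnexin gene, rose from 0.188 ± 0.0810 to 3.46 ± 0.752 FPKM, and CG32523 from 1.62 ± 0.5003 to 9.23 ± 0.566 FPKM. CG33666 rose from 0.315 ± 0.278 to 4.32 ± 0.763 FPKM (12 and 169 reads, ratio 13.5, 95% interval 7.54 to 26.7). CG33665 beside it fell from 16.1 ± 4.64 to 3.34 ± 1.47 FPKM. Both overlap CG42340 on the same strand, and the call of CG33665 was lost without control replicate 2 (adjusted p = 0.0839) or 3 (0.0622). Falls on the X also included CG32750, from 17.5 ± 1.73 to 4.55 ± 0.640 FPKM, and sordd2, from 30.8 ± 1.39 to 11.5 ± 2.05 FPKM.

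**Figure D2:**
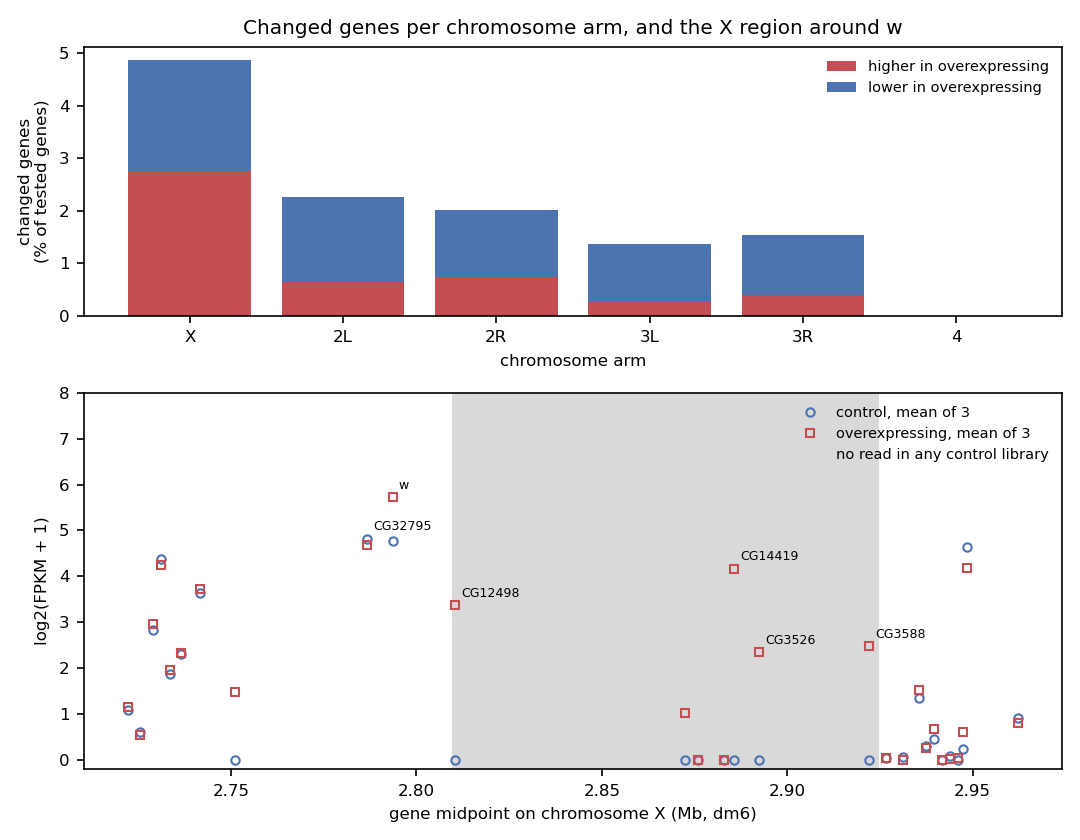
Top, share of tested genes that changed per chromosome arm (percent), split into higher and lower in the overexpressing flies; the X stands at 4.88%. Bottom, mean log2(FPKM + 1) of 3 control (circles) and 3 overexpressing (squares) libraries for genes around w on the X (dm6, Mb). The shaded stretch holds 7 genes with 0 reads in the control libraries, 5 of them read in the overexpressing libraries. The gene kirre, which spans the stretch and had reads in both groups, is not drawn.

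The antimicrobial peptide genes were the readout that the series names. Of 18 tested members limma called 3 higher and 0 lower, and voom on recovered reads called 7 higher and 0 lower. CecA2, which encodes a cecropin, rose 3.54-fold from 93.3 ± 11.2 to 330.0 ± 62.7 FPKM (log2 change 1.80 ± 0.15 SE, adjusted p = 0.00173). Def, which encodes defensin, a peptide that acts on Gram-positive bacteria, rose 1.90-fold from 996 ± 174 to 1897 ± 288 FPKM (adjusted p = 0.0261), and AttC, an attacin gene, rose 1.50-fold from 2162 ± 260.2 to 3237 ± 159 FPKM (adjusted p = 0.0249). CecA1, AttD and CecB did not pass. CecA1 stood at 549 ± 129 and 1145 ± 325 FPKM, AttD at 90.2 ± 14.2 and 207 ± 85.0 FPKM, and CecB at 34.0 ± 11.2 and 76.4 ± 15.5 FPKM (adjusted p = 0.0867, 0.0763 and 0.0632). The most abundant members did not pass. DptA, a diptericin gene, stood at 12162 ± 1437 and 12883 ± 652 FPKM, Dro, the drosocin gene, at 7643 ± 882 and 7983 ± 237 FPKM, and Mtk, the metchnikowin gene, at 9111 ± 462 and 7762 ± 482 FPKM (SD, n = 3 each; adjusted p = 0.740, 0.795 and 0.206). The groups of Mtk did not overlap, and it was the member lower when adjusted over the list alone. DptB, AttA, AttB, CecC, Anp, Drsl2, Drsl3, Drsl4 and Drsl5 did not pass, at log2 changes of -0.04, -0.13, 0.57, 0.63, 0.11, 0.34, 0.30, 0.29 and 0.13. Drsl1 and Drsl6 were below the filter. Without 1 library, CecA2 passed in all 6 fits. AttC was lost without control replicate 2 or 3 or overexpressing replicate 1 or 3 (adjusted p up to 0.114), and Def in every fit but that without overexpressing replicate 2 (adjusted p up to 0.0967). Without that library CecA1 (0.0156) and AttB (0.0344) passed as well. The list's median log2 change was 0.32, with 15 members above 0 and 3 below. Camera put it above other genes (adjusted p = 2.02e-05), and the call was lost with an estimated correlation (adjusted p = 0.346 with an estimated correlation of 0.216). Fry gave an adjusted p of 0.126 one way and 0.00274 for change in either direction. Adjusted over the list alone, 8 members were higher and 1 lower. The identifier FBgn0010381, with no symbol in the annotation used here, had a higher level than any of these. Its solved exon length of 387 nt is that of 2 annotated genes whose identifiers the table lacks: Drs, which encodes drosomycin, a main Toll readout, and lncRNA:CR46496. The name was therefore not assigned. It stood at 18111 ± 325 FPKM in controls and 17525 ± 985 in overexpressing libraries (adjusted p = 0.825).

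Bomanin and related Toll-induced peptide genes went the other way on balance. Of 21 tested members limma called 0 higher and 2 lower, and voom on recovered reads called 0 higher and 7 lower, among them BomS2, BomS6, BomT3 and BomBc2. The 2 called by limma were SPH93, a serine protease homologue gene, from 57.6 ± 6.22 to 23.2 ± 4.95 FPKM (log2 change -1.29 ± 0.14 SE, adjusted p = 0.00599), and CG45045, from 2515 ± 103 to 1928 ± 76.5 FPKM (adjusted p = 0.0246). The Bomanins themselves did not pass by limma. BomS1 stood at 6933 ± 347 and 6474 ± 403 FPKM, BomS2 at 3438 ± 192 and 2478 ± 310 FPKM, and BomBc1 at 1513 ± 157 and 1640 ± 158 FPKM (SD, n = 3 each; adjusted p = 0.600, 0.0578 and 0.647). BomS3, BomS4, BomS5, BomS6, BomT1, BomT2, BomT3, BomBc2 and BomBc3 did not pass, at log2 changes of -0.05, -0.13, -0.32, -0.39, 0.21, -0.23, -0.37, -0.32 and -0.09. Bbd, IM33, IBIN, BaraA1 and BaraC did not pass, at log2 changes of -0.18, 0.16, -0.25, -0.36 and -0.05. BaraB and IM18 were below the filter. Of the Daisho genes, Dso1 stood at 1308 ± 129 and 1025 ± 81.1 FPKM and Dso2 at 393 ± 45.5 and 608 ± 166 FPKM, neither past the threshold. SPH93 passed without each library, and CG45045 only without overexpressing replicate 2 (highest adjusted p 0.130, without overexpressing replicate 1). Without overexpressing replicate 2 BomS2 (0.0155), BomT3 (0.0214) and BomS6 (0.0454) also passed as lower and Dso2 (0.0136) as higher. The list's median log2 change was -0.23, with 17 of 21 members below 0 (camera adjusted p = 0.000196; adjusted p = 0.326 with an estimated correlation). Fry gave adjusted p of 0.0734 one way and 0.00385 in either direction, and 1 member was higher and 8 lower when adjusted over the list alone. The difference between the list means of antimicrobial peptides and of these genes, taken per library on the log2 scale, was -0.70 ± 0.20 in controls and -0.01 ± 0.13 in overexpressing libraries (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible).

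**Figure D3:**
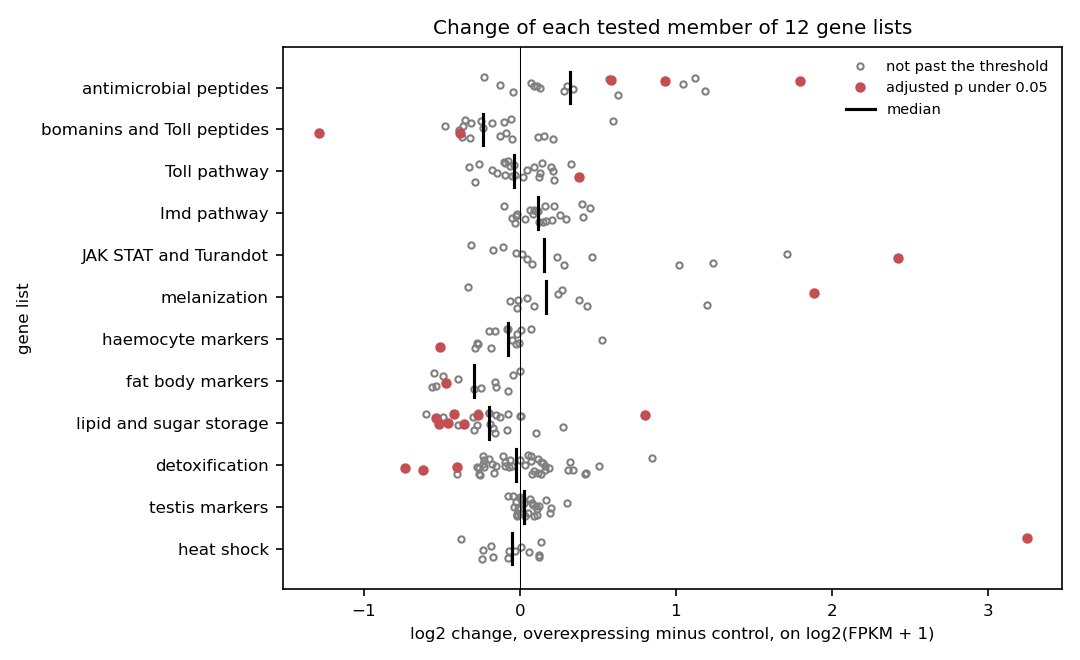
Log2 change, overexpressing minus control on log2(FPKM + 1), of every tested member of 12 gene lists (one point per gene; filled points have an adjusted p under 0.05, bars are medians). The antimicrobial peptide median lay at 0.32, the Bomanin and Toll peptide median at -0.23 and the fat body marker median at -0.30.

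Among 24 Toll pathway components limma called 1, and voom called 1 higher and 3 lower. PGRP-SD, which encodes a peptidoglycan recognition protein, rose 1.30-fold from 490.1 ± 25.1 to 639 ± 43.8 FPKM (adjusted p = 0.0381), a call held in 1 of 6 fits with a library left out, that without overexpressing replicate 2 (highest adjusted p 0.134). The other 23 did not pass by limma. Of these Dif, dl and spz were chosen after their values were seen: Dif and dl, the NF-kB factors of the pathway, had log2 changes of -0.10 ± 0.06 and -0.27 ± 0.07 (SE; adjusted p = 0.455 and 0.135), and spz, the gene of the Toll ligand, at 0.33 ± 0.09 (adjusted p = 0.127). The list's median was -0.04 and its mean 0.005, and camera gave an adjusted p of 0.799. The median was -0.0006 without control replicate 1 and -0.02 without control replicate 2 or overexpressing replicate 3. Adjusted over the list alone, 4 members were higher and 3 lower, and fry's p for change in either direction was 0.00385. Of 22 Imd pathway components limma called 0, with 7 at an unadjusted p under 0.05 and 2 called by voom; the median log2 change was 0.12 (camera adjusted p = 0.0019; adjusted p = 0.346 with an estimated correlation), and 1 member was higher when adjusted over the list alone. PGRP-SC2, which passed without control replicate 1 (0.0195), stood at 381 ± 59.0 and 498 ± 6.09 FPKM and PGRP-SB1 at 1175 ± 106 and 1261 ± 101 FPKM.

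TotM, a Turandot stress peptide gene, was the 1 of 14 JAK-STAT and Turandot genes that limma called higher, and 1 member was higher adjusted over the list alone. TotM rose from 9.11 ± 2.09 to 64.3 ± 52.6 FPKM (adjusted p = 0.0485). Its spread in the overexpressing group was nearly as large as its mean, and the call held without overexpressing replicate 2 and was lost without each other library (adjusted p up to 0.156). Voom called 0 of the 14. The list's median log2 change was 0.16, with 10 members above 0 and 4 below. Camera gave the list an adjusted p of 0.0677, with values under 0.05 without control replicate 1 (0.0427) or 2 (0.0154) or overexpressing replicate 2 (0.00306) or 3 (0.0356). It was also under 0.05 with replicate number as a block (0.0218), with no filter (0.0146), with voom (0.0422) and without X-linked genes (0.0402). Of 12 melanization genes Ddc, which encodes dopa decarboxylase, rose from 24.9 ± 5.09 to 100.4 ± 42.3 FPKM (adjusted p = 0.0295), again held without overexpressing replicate 2 alone (adjusted p up to 0.114). Voom called 3 higher and 1 lower. Melanization genes had a median of 0.17 (camera adjusted p = 0.0192; adjusted p = 0.602 with an estimated correlation), lost without control replicate 3 (0.0533) or overexpressing replicate 3 (0.112). The median was 0.09 without overexpressing replicate 3. Adjusted over the list alone, 5 were higher and 1 lower. Of 16 haemocyte markers NimC1, a phagocytosis receptor gene, fell from 4.93 ± 0.198 to 3.16 ± 0.180 FPKM (adjusted p = 0.0207; lost without each library but overexpressing replicate 2, up to 0.0916). Voom called 1 higher and 1 lower. The haemocyte median was -0.08 (camera adjusted p = 0.0251; adjusted p = 0.481 with an estimated correlation). It was -0.13 without control replicate 3, -0.13, -0.14 and -0.12 without overexpressing replicate 1, 2 and 3. Adjusted over the list alone 1 was higher and 4 lower.

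Fat body markers and genes of lipid and sugar storage lay below 0. The fat body is the insect's liver-like organ and a main source of circulating immune peptides. Of 13 fat body markers fat-spondin fell, from 34.8 ± 1.06 to 24.8 ± 0.730 FPKM (adjusted p = 0.00668), and passed without each library; the median was -0.30 with 12 of 13 below 0, and it was -0.47 without control replicate 3, -0.48 without overexpressing replicate 2 and -0.19 without overexpressing replicate 3 (camera adjusted p = 0.000757; adjusted p = 0.326 with an estimated correlation), and 2 were lower when adjusted over the list alone. Of 27 lipid and sugar storage genes limma called 6 lower and 1 higher, where voom called 8 lower and 1 higher. ACC, acetyl-CoA carboxylase, fell from 74.7 ± 5.27 to 51.8 ± 1.22 FPKM, fbp, fructose-1,6-bisphosphatase, from 58.6 ± 1.72 to 40.0 ± 1.33 FPKM, and mdy, a diacylglycerol acyltransferase gene, from 11.5 ± 0.362 to 8.10 ± 0.859 FPKM (adjusted p = 0.00943, 0.00334 and 0.0354). Desat1, FASN2 and Tps1, chosen after their values were seen, also fell, with log2 changes of -0.36, -0.27 and -0.42. Thor, which encodes the translation repressor 4E-BP, rose from 316 ± 25.3 to 560 ± 112 FPKM (adjusted p = 0.0369). The list's median was -0.20 (camera adjusted p = 4.24e-08; adjusted p = 0.326 with an estimated correlation), and adjusted over the list alone 2 were higher and 15 lower. Without 1 library fbp passed in all 6 fits, ACC in all but that without control replicate 2 (adjusted p = 0.0519), and mdy and Thor only without overexpressing replicate 2 (adjusted p up to 0.130 and 0.129).

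Of 12 glycolytic genes Hex-C, hexokinase C, fell from 66.8 ± 4.19 to 40.9 ± 1.28 FPKM (adjusted p = 0.00235), a call held without each library; camera gave the list an adjusted p of 0.432, and 1 member was lower adjusted over the list alone. Of 44 detoxification genes limma called 3 lower. Cyp6g1, a cytochrome P450 gene, fell from 117 ± 4.80 to 76.0 ± 4.88 FPKM (adjusted p = 0.00404). GstE7, a glutathione S-transferase gene, fell from 39.6 ± 4.83 to 23.3 ± 1.47 FPKM, and GstE8 from 16.5 ± 1.52 to 12.2 ± 0.0430 FPKM (adjusted p = 0.0112 and 0.0375). Cyp6g1 passed without each library, GstE7 was lost without control replicate 1 (0.0534) or overexpressing replicate 3 (0.0542), and GstE8 was lost in every such fit (adjusted p up to 0.127). Camera gave detoxification genes an adjusted p of 0.440, with 1 higher and 6 lower adjusted over the list alone. Of 34 cuticle protein genes Cpr66Cb fell from 3.90 ± 0.146 to 1.15 ± 0.335 FPKM and Cpr51A from 20.02 ± 1.32 to 15.2 ± 0.602 FPKM (adjusted p = 0.00576 and 0.0369); the first passed without each library and the second in 2 of 6 fits, those without control replicate 3 and overexpressing replicate 2 (adjusted p up to 0.140). The cuticle list had a median of -0.13 (camera adjusted p = 0.00781; adjusted p = 0.395 with an estimated correlation; 5 lower adjusted over the list alone). Without control replicate 1 the median was -0.05. With no filter on low values it was -0.02 and the call was lost (adjusted p = 0.445).

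Of 30 testis markers limma called 0, with 2 at an unadjusted p under 0.05 and 0 called by voom; the median was 0.02 and camera gave an adjusted p of 0.0956 (0.00721 without control replicate 3, 0.0176 without overexpressing replicate 1, 0.0303 under quantile normalization). The testis median was 0.06 without control replicate 3, 0.05 without overexpressing replicate 1, -0.01 without control replicate 2 and -0.01 without overexpressing replicate 2. Mst84Db stood at 724 ± 34.6 and 715 ± 50.9 FPKM and S-Lap1 at 683 ± 22.6 and 693 ± 28.8 FPKM. Limma called 0 of 36 accessory gland genes (6 at an unadjusted p under 0.05, 0 by voom; median -0.09, camera adjusted p = 0.0926, and 0.00214 without control replicate 2, 0.0316 without overexpressing replicate 1, 0.039 with sample weights), with Sfp87B at 1701 ± 148 and 1590 ± 191 FPKM and Obp56g at 1214 ± 126 and 1172 ± 57.3 FPKM. The accessory gland median was -0.03 without control replicate 1, -0.04 without control replicate 3 and -0.02 without overexpressing replicate 3. Limma called 0 of 43 gut digestive enzyme genes (6 at an unadjusted p under 0.05, 1 by voom), with alphaTry at 2918 ± 127 and 3065 ± 98.7 FPKM and Jon65Aiv at 1720 ± 298 and 1610 ± 94.6 FPKM; the gut median was -0.15 (camera adjusted p = 0.00742, lost without control replicate 1 at 0.0747; adjusted p = 0.429 with an estimated correlation). The gut median was -0.09 without overexpressing replicate 3. Limma called 0 of 24 muscle markers (2 at an unadjusted p under 0.05, 0 by voom), with Mlc2 at 710.0 ± 91.2 and 748 ± 10.9 FPKM and Act57B at 435 ± 58.0 and 454 ± 59.6 FPKM. The muscle median of 0.08 had a camera adjusted p of 0.048 (adjusted p = 0.780 with an estimated correlation); its direction turned without control replicate 3 (median -0.01, adjusted p = 0.732) and its median was 0.14 without control replicate 2, and the call was lost without overexpressing replicate 1 (0.129) or 3 (0.112). The muscle call was also lost with no filter (0.0538), at a mean FPKM of at least 5 (0.0524), with no trend (0.0674), with sample weights (0.0676) and without X-linked genes (0.0519). Limma called 0 of 18 neuron markers (1 at an unadjusted p under 0.05, 1 by voom; median 0.03, and 0.01 without control replicate 3 or overexpressing replicate 1; camera adjusted p = 0.294), with nSyb at 44.2 ± 1.22 and 45.2 ± 2.26 FPKM and Csp at 41.3 ± 1.58 and 41.3 ± 0.427 FPKM. No member of these 5 lists passed when adjusted over the list alone. Of 21 photoreceptor markers Rh2, an opsin gene of the ocelli, rose from 19.95 ± 0.186 to 27.7 ± 2.995 FPKM (adjusted p = 0.0369; 1 higher adjusted over the list alone), held in 1 of 6 fits, that without overexpressing replicate 2 (up to 0.133); the list's median was 0.07 (camera adjusted p = 0.0101, lost without overexpressing replicate 1 at 0.283 and a median of 0.03; adjusted p = 0.773 with an estimated correlation). Of 20 female markers listed, 3 passed the filter and Yp3 fell. The median was -0.39 (camera adjusted p = 0.00386; adjusted p = 0.326 with an estimated correlation; 2 lower adjusted over the list alone). With no filter on low values the female marker median was 0.04 and the call was lost (adjusted p = 0.905). Obp58c was the 1 of 33 odorant-binding protein genes that limma called higher, from 0.108 ± 0.127 to 1.24 ± 0.245 FPKM (adjusted p = 0.022). It had 4 control and 50 overexpressing reads, a ratio of 12.0 (95% interval 4.4 to 45.8). The call was lost without control replicate 1 (0.0778) or 2 (0.0842). The list gave a camera adjusted p of 0.590 (0.0144 without overexpressing replicate 2), with a median of -0.01 (-0.07 to 0.003 over the 6 fits without 1 library) and a mean of 0.03, and 1 member higher and 1 lower adjusted over the list alone.

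Limma called 0 of 86 ribosomal protein genes (3 at an unadjusted p under 0.05, 0 by voom), with RpL41 at 3341 ± 141 and 3144 ± 209 FPKM and RpL23 at 1604 ± 14.7 and 1567 ± 57.8 FPKM; the median was -0.05 (camera adjusted p = 0.0271; adjusted p = 0.780 with an estimated correlation), and the call was also lost under quantile normalization (0.481), with replicate number as a block (0.0612), with sample weights (0.255), at a mean FPKM of at least 5 (0.0524) and without control replicate 2 (0.155) or 3 (0.0528) or overexpressing replicate 1 (0.0852) or 2 (0.776). The ribosomal median was -0.02 without overexpressing replicate 2 and -0.08 without overexpressing replicate 3. Of 87 nuclear oxidative phosphorylation genes limma called 0 (5 at an unadjusted p under 0.05, 1 by voom), with ATPsynbeta at 977 ± 54.2 and 1013 ± 32.4 FPKM and ND-MLRQ at 1075 ± 67.6 and 1063 ± 36.6 FPKM; the median was 0.03 (camera adjusted p = 0.0271; adjusted p = 0.773 with an estimated correlation), lost without control replicate 1 (0.274) or 3 (0.149) or overexpressing replicate 3 (0.112). The median was 0.01 without control replicate 1, 0.06 without control replicate 2 and 0.02 without control replicate 3. Of 24 mitochondrial genome genes mt:srRNA rose from 267 ± 30.8 to 453 ± 56.5 FPKM and mt:ND4 fell from 880 ± 14.4 to 634 ± 50.6 FPKM (adjusted p = 0.0191 and 0.0172; camera adjusted p = 0.761; 3 higher and 2 lower adjusted over the list alone). Both depended on the libraries used: mt:srRNA was lost without control replicate 2 or 3 or overexpressing replicate 1 (up to 0.0884) and mt:ND4 without each library but overexpressing replicate 2 (up to 0.0819). Prosalpha4, on the X, was the 1 of 48 proteasome genes that limma called lower, and 1 was lower adjusted over the list alone. Prosalpha4 fell from 137 ± 3.04 to 104 ± 3.13 FPKM (adjusted p = 0.0105). That call was lost without control replicate 2 (0.0591) or overexpressing replicate 1 (0.0558) or 3 (0.0525). The list's median was -0.07 (camera adjusted p = 0.00368; adjusted p = 0.536 with an estimated correlation). Limma called 0 of 10 clock genes (1 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone; camera adjusted p = 0.681), with cry at 82.1 ± 3.36 and 75.6 ± 5.42 FPKM and to at 31.9 ± 1.78 and 30.1 ± 0.917 FPKM. The 1 tested histone gene, His2B:CG33868, stood at 4.15 ± 0.519 and 4.28 ± 1.47 FPKM.

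Hsp70Bb was the 1 of 14 tested heat shock genes that limma called higher, and voom called 1 higher and 2 lower. The near-identical copies Hsp70Bbb and Hsp70Bc, like the copies below chosen after their values were seen, did not pass. Hsp70Bbb had a log2 change of -0.18 and Hsp70Bc one of -0.08. Hsp70Ba, a copy below the filter, had 28, 30 and 9 reads in the control libraries and 58, 79 and 39 in the overexpressing libraries, without overlap. Hsp70Ab, also below the filter, had 15, 30 and 14 against 36, 46 and 16. The list's median was -0.05 and its mean 0.17, and the median was -0.01 without control replicate 2, -0.11 without overexpressing replicate 1 and 0.02 without overexpressing replicate 2. Camera pointed down (adjusted p = 0.761) where fry pointed up (0.357). Adjusted over the list alone 1 member was higher and 4 lower. Among transgene markers, w, whose shortened form marks many transgenes, rose 1.98-fold from 26.2 ± 1.38 to 51.9 ± 4.19 FPKM (adjusted p = 0.00135), and v, the vermilion eye colour gene, fell from 38.8 ± 0.400 to 27.4 ± 0.520 FPKM (adjusted p = 0.00372); both passed without each library. The body colour gene y was below the filter, at 0.392 ± 0.220 and 0.237 ± 0.172 FPKM. Msp300, the gene beside attP40, stood at 8.30 ± 0.419 and 7.74 ± 0.393 FPKM (adjusted p = 0.608).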

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

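The alternatives with voom, without X-linked genes and with the unpaired identifier were chosen after seeing the data; the others were planned. All 274 changed genes, or those of them that remained testable, kept their direction under every alternative, and the count stayed between 191 and 273 with a pseudocount of 0.1, no filter, a mean FPKM of at least 5, either other scaling and no trend. Median-of-ratios scaling moved almost nothing, since the deposited values already lie near that scale. The count was 415 with sample weights (261 lower), 456 with voom (159 higher and 297 lower), 123 without X-linked genes (30 higher and 93 lower, from fewer genes), and 66 with an absolute log2 change of at least 1 as a further condition. Without 1 library it ran from 70 to 431, from 23 to 177 higher and from 38 to 254 lower; with fewer libraries the test has less power, while the rise to 431 came without overexpressing replicate 2, the library that stood apart. Genes near 0 in the controls fell below the filter when an overexpressing library was left out, so 247 of the 274 were testable there. With replicate number as a block the count was 110 (44 higher and 66 lower), 100 of them among the 274. Libraries of the same number did not deviate together (residual correlations -0.05, -0.18 and 0.03), which gave no sign of pairing by number. So few correlations cannot exclude pairing, and replicate 3 had the fewest recovered reads in both groups. Except where stated, the cause of a change between settings was not tested.

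CR33942 kept its call under every alternative, at log2 changes between 4.80 and 4.90. The antimicrobial peptide median stayed at 0.32 and the Bomanin and Toll peptide median at -0.23 with an estimated correlation, but both calls ended there (adjusted p = 0.346 and 0.326); under all other settings both lists passed. With the unpaired identifier the antimicrobial peptide median was 0.30 (adjusted p = 6.46e-05). The Toll pathway median passed under no setting and ran from -0.0517 to -0.000636 without 1 library. The muscle marker list turned direction without control replicate 3 (median -0.0149, adjusted p = 0.732); its medians without 1 library ran up to 0.138. The female marker and cuticle protein lists lost their calls with no filter (medians 0.04 and -0.02). With an estimated correlation 13 more lists lost their call. Of 52 named genes that were called besides CR33942, 27 were called in every alternative in which they were tested, and of 61 not called, 50 were called in none. Counting error is small for genes above a few FPKM; below that, as for the genes with 16 or fewer reads in a group, the interval on the reads is wide.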

Other observations

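Several enzymes of purine synthesis and of folate-linked one-carbon metabolism were among the genes that fell. All genes named in this paragraph were chosen after their values were seen, and fat body markers lay below 0 in the same libraries (median -0.30, 12 of 13). Paics fell from 103 ± 3.10 to 62.5 ± 5.65 FPKM and Pfas from 26.9 ± 1.14 to 20.8 ± 1.11 FPKM, both steps of purine synthesis. Shmt, serine hydroxymethyltransferase, fell from 50.2 ± 0.893 to 37.0 ± 2.08 FPKM, pug from 60.2 ± 2.04 to 42.1 ± 2.92 FPKM and Gnmt, glycine N-methyltransferase, from 322 ± 9.98 to 193 ± 25.5 FPKM. Galk and Galt, galactokinase and galactose-1-phosphate uridylyltransferase, for which no list was tested, fell from 43.1 ± 0.351 to 30.6 ± 2.69 FPKM and from 50.5 ± 2.32 to 37.2 ± 2.39 FPKM (SD, n = 3 each; limma adjusted p between 0.00366 and 0.0333 for these 7). Among the rises outside the fixed lists, Pu, GTP cyclohydrolase, went from 83.8 ± 15.7 to 161 ± 16.1 FPKM, edin, an infection-induced peptide gene, from 1409 ± 179 to 2218 ± 286 FPKM, and MSBP, on the X, from 58.3 ± 1.45 to 148 ± 8.24 FPKM. A hypothesis, written before their values were seen, was that members of purine and one-carbon metabolism not seen among the called genes fell as a list. Mthfs and CG3999, also called lower (log2 changes -0.53 and -0.56), are not in that list either. The 12 tested members had a median log2 change of -0.13, with 7 of them below 0. That limma called 0 of them followed from how they were chosen. Camera gave p = 0.0429 at the preset correlation. That met the rule as first written, a p under 0.05 with a negative median. With an estimated correlation p was 0.149, and the need for this second p was added after both were seen, so a fall across the pathway may be present but stays open.

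The tests below were chosen after the results they bear on were seen, except those of the whole X chromosome, of single libraries and of the other splits. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 274 changed genes; the highest count of any other split was 0, with up to 965 genes at an unadjusted p under 0.05. With 10 splits a share under 0.05 cannot be reached. The bootstrap intervals given below resample genes, which are not independent, so they do not cover the spread between libraries.

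The concentration of changed genes on the X was weighed against technical and strain explanations. A shift of the whole chromosome through scaling or dosage is argued against by the median log2 change of X-linked genes, which lay -0.00112 from the autosomal median (bootstrap 95% interval -0.0117 to 0.00559). A different share of testis RNA is argued against by the testis markers, whose median log2 change was 0.0246 (interval over genes 0.0006 to 0.0824). For the neighbours of w, a deletion on the X chromosome of the control flies is a candidate explanation that was not tested, since these genes were picked for lying together without control reads, which made each test tried on them void. One deletion of that stretch would leave out lncRNA:CR43494, chosen after its values were seen, which had 0 control and 52 overexpressing reads on the other side of w. Between them CG32795 and w stood at 27.2 ± 0.342 and 26.2 ± 1.38 FPKM in controls. Control reads of w may come in part from transgenes, many of which are marked by its shortened form. The gene kirre, which spans the stretch and was also chosen after its values were seen, had 488 control and 885 overexpressing reads. It stood at 1.11 ± 0.0802 and 1.94 ± 0.149 FPKM (limma adjusted p = 0.0746). These values do not show where in kirre the reads lay. For the other X-linked genes, different X chromosomes in the strains cannot be told apart from an effect of CR33942, since each group has its own strain and the labels give no direction of the crosses; the odds of lying on the X were higher among changed genes past an absolute log2 change of 1 than among smaller changes (Fisher's exact odds ratio 4.53, 95% interval 2.44 to 8.55), and an effect of the overexpression was not tested separately. That this odds ratio cannot favour the strains, being confounded, was settled only after its value was seen.

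Hsp70Bb was the only heat shock gene called by limma. Voom called 1 higher and 2 lower, and adjusted over the list alone 1 was higher and 4 lower, while Hsp70Ba, below the filter, also had more reads in every overexpressing library than in any control library. The other 13 tested heat shock genes had a median log2 change of -0.0685 (bootstrap 95% interval -0.184 to 0.0586). Hsp70Bb had been picked as the only one called, so it was known in advance that the others had changed little. Their median therefore does not test heat or protein stress, which stays open. An exchange of counted reads between near-identical copies is argued against by the reads summed over 6 Hsp70 copies. They were higher by a log2 ratio of at least 1.94 in every pair of an overexpressing and a control library. The sum holds only reads assigned to a gene. It cannot tell whether reads left unassigned in the controls were assigned to Hsp70Bb in the overexpressing libraries. Hsp70 sequence carried by the transgene vector may add reads to this copy, as many Gal4-driven vectors hold an Hsp70 promoter; w, another gene that vectors carry, had a log2 change of 0.959, but both could also come with the strain, and the vector's sequence was not used here. An effect of CR33942 on Hsp70Bb was not tested separately.

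The antimicrobial peptide list lay above 0 and the Bomanin and Toll peptide list below, by tests with limits: the difference between them had an exact p of 0.1, both list calls ended with an estimated correlation (adjusted p = 0.346 and 0.326), and fry gave 0.126 and 0.0734 one way. A lower share of fat body RNA in the overexpressing libraries would lower antimicrobial peptide genes, which had already been seen to lie above 0. Their median log2 change lay 0.617 above that of the fat body markers (bootstrap 95% interval 0.329 to 1.10), a difference known in advance from the 2 medians. It therefore does not test such a share for these genes. The fat body median itself ran from -0.48 to -0.19 without 1 library, below 0 throughout. The groups overlapped, though, in the mean log2(FPKM + 1) of these markers per library. It was 4.32, 3.91 and 3.70 in control replicates 1, 2 and 3, and 3.68, 3.84 and 3.49 in the overexpressing ones. For the Bomanins a lower share of fat body RNA stays open: their median lay 0.0634 from that of the fat body markers (interval -0.159 to 0.373), and 6 of the 16 listed markers also stand in another list. A single library as the source is argued against, since the difference of the medians was at least 0.473 without any 1 library. An effect of CR33942, or of the strain, on antimicrobial peptide genes may remain, and these libraries do not separate the 2.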
